A study of Mus musculus with 6 samples.

How the data were processed

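The data were 6 arrays of sorted mouse colonic Tregs, 3 labelled GPR15-GFP+ and 3 labelled GPR15-GFP-. Per the labels, lymphocytes were freed from the colonic lamina propria with collagenase, stained for CD4, sorted directly into lysis buffer, and their RNA was labelled with biotin for a 1-colour Affymetrix array with a kit made for very small amounts of RNA. The authors deposited log2 values summarised per probe set by RMA (background correction, quantile normalization and summarisation of probes), per the submitters' processing notes, which name no software version. The values fitted that description: each array's values lay between 2.85 and 13.1 with medians of 6.49 to 6.64. The array's name, the genome build of its annotation and any detection calls were not given in the sources used here, so no coordinates are printed and no signal-over-background filter was set. RMA's quantile step gives arrays like distributions, yet the arrays differed in spread, and the arrays numbered 1 were narrower (SD 1.63 in both fractions) than the other 4 (SD 1.74 to 1.87).

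The table held 22142 rows. The platform annotation gave 19527 rows 1 gene symbol, 0 several and 2615 none, and the latter were not used in the gene tests. All 19527 gene identifiers were found in the reference gene table (assembly GRCm38.p6), and 0 symbols were updated. Of the genes, 33 had more than 1 row, and the row with the highest mean over the 6 arrays was taken, which left 19494 genes.

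Groups were taken from the sample titles and the reporter phenotype in the labels. Differences are samples labelled GPR15+ minus samples labelled GPR15-, in log2 units. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are limma's moderated ones. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over 24 lists. Where the correlation is estimated instead, camera also takes the few residual degrees of freedom that the arrays leave, not those of all genes. A call lost under that setting can therefore stem from either change. The lists covered Treg identity, activated and effector Treg, tumour-infiltrating Treg, naive and central memory T cell, Th17, Th1, Th2, homing receptors and integrins, T cell receptor-induced genes, immediate-early and dissociation stress, cell cycle, type I interferon, glycolysis, oxidative phosphorylation, fatty acid and lipid uptake, and cytosolic ribosomal proteins. Marker lists covered T cells, CD8 T and NK cells, γδ T and innate lymphoid cells, B and plasma cells, macrophages with monocytes and granulocytes, dendritic cells, epithelial cells, and fibroblasts with endothelial and smooth muscle cells. A list of mitochondrially encoded genes had 0 measured genes. Foxp3, Gata3 and Tcf7 were not analysed here.

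The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Gpr15, Foxp3, Ptprc and Cd4 always. In each direction it named the 12 genes with the largest difference among those that passed without overlap, filled by the smallest unadjusted p where fewer passed, as happened for all 24. From each list it named up to 4 members, first those that passed over all genes, then those that passed over the list alone, then those with the largest difference. Predicted genes, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments were not named under the second part. Genes named outside the rule were Il23r, Rora, Tmem176a, Il17a, Foxp1, Ccr7, Il7r, Lgals4, Cdh1 and Muc2, chosen after their values were seen or for their high level in a list. Uty was also named outside it, for the check of pairing.

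The equal numbers in both fractions were checked for pairing. Deviations from the group means correlated between samples of equal number at 0.567, 0.381 and 0.319 for the numbers 1, 5 and 6, all above 0.1, so the numbers were taken to pair the samples. GPR15- replicate 6 with GPR15+ replicate 5 also passed that mark at 0.315, as did GPR15- replicate 5 with GPR15+ replicate 6 at 0.213. The correlations thus set the number 1 apart and hardly part 5 from 6. The Y-linked gene Uty lay at 7.48 and 7.65 in the samples numbered 1, at 8.29 and 8.97 in those numbered 5, and at 4.60 and 4.27 in those numbered 6, which also parts the numbers and not the fractions. The samples numbered 6 therefore did not come from the same animal or pool as those numbered 1 and 5. Values with the number as a block are given where they changed a call or moved a count by over 1.5 times. The labels do not say whether the numbers mark animals or pools, nor whether 1 and 5 were separate, so p-values measure only the spread between these samples. With 3 arrays a fraction, an exact permutation test of a single gene could not go below 0.1 (2-sided), so limma's moderated test was used.

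The alternatives fixed beforehand were a filter on the 40% dimmest genes, eBayes with trend and robust settings, the replicate block, quantile normalization of the deposited values again, centring of arrays on their medians, every row as its own feature, the mean of a gene's rows, array weights, each array left out in turn, camera with an estimated correlation, fry in place of camera, treat with a minimum fold of 1.2, and an unadjusted p under 0.05 with at least 2-fold difference. Chosen after seeing the data were leaving out both arrays numbered 1, removal of the intensity trend (a lowess curve with a span of 0.3 per array), and the block combined with that removal, with the eBayes settings, with the dim filter and with the estimated correlation. The scripts were tested on 5 simulated data sets of 19494 genes with 200 changed genes each, which gave a mean of 6 false calls per set. A list shifted by 0.5 was called in 5 of 5 sets, with 0 false list calls. The simulated noise was independent between genes and arrays, without pairing or intensity trend. The simulation therefore does not show how often camera calls lists falsely on the real arrays.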

Results

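Gene expression was measured on 1-colour Affymetrix arrays in regulatory T cells (Tregs) sorted from the tumorous colonic lamina propria of mice with chemically induced colorectal cancer. The tumours followed azoxymethane, a carcinogen, and dextran sulfate sodium, which inflames the colon. The mice carried a red reporter of Foxp3, the transcription factor that defines Tregs, and a green reporter of GPR15, a receptor that guides T cells to the colon. CD4-stained, red cells were sorted into GPR15-GFP+ and GPR15-GFP- fractions. The data comprised 3 arrays per fraction, and the samples of both fractions were numbered 1, 5 and 6. Median log2 values of the 6 arrays lay between 6.49 and 6.64. The arrays numbered 1 had the narrowest spread of values, with SDs of 1.63 in both fractions against 1.74 to 1.87 on the other 4 arrays. The number of arrays limits the precision of every value below.

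The comparison asked how tumour-associated Tregs that carry GPR15 differ in expression from those that do not. In samples labelled GPR15+, a list of naive and central memory T cell genes was higher, with a median log2 difference of 0.50 over 14 genes, and so was a list of Th17 genes, at 0.22 over 15 genes. Within the Th17 list 5 members passed adjusted over the list alone, and none over all genes: the membrane protein gene Tmem176b (1.38), the interleukin-1 receptor Il1r1 (1.22), the chemokine Ccl20 (0.98) and the interleukin-23 receptor Il23r (0.61) above 0, and the cytokine Csf2 (-0.67) below. A list of epithelial genes was lower, at -0.25 over 17 genes. With the correlation between members estimated from these arrays, none of the 3 lists was called (camera adjusted p = 0.270, 0.270 and 0.491). That setting also cuts the test's degrees of freedom to the few that the arrays leave, which by itself makes calls harder. Of 19494 genes tested with limma, 0 were higher and 0 lower after adjustment over all genes, and the smallest adjusted p was 0.540.

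At an unadjusted p under 0.05, limma found 544 genes higher and 670 lower in samples labelled GPR15+, or 1214 in all against 974.7 expected by chance for independent arrays. After each array was centred on its median these counts were 796 and 421. With the replicate number as a block, 0 genes passed the adjusted threshold, the smallest adjusted p from limma was 0.0750, and 2411 genes had an unadjusted p under 0.05. Leaving out 1 array moved the unadjusted total to between 668 and 4351, the highest without GPR15+ replicate 1. In simulated data of the same size, drawn without pairing or correlation between genes, limma without a block recovered 29.6% of genes changed by 1 log2 unit. It recovered 82.1% of those changed by 2 and 95.8% of those changed by 3. Of 24 gene lists, camera called 7, of which 6 were higher and 1 lower. With the correlation between list members estimated from these arrays, 0 lists were called and the lowest adjusted p from camera was 0.270. Without GPR15- replicate 1 camera called 2 lists, and without GPR15+ replicate 5 it called 1.

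Gpr15 itself, the gene behind the green reporter, lay lower in the samples labelled GPR15+, at 8.12 ± 0.23 (SD, n = 3) against 8.78 ± 0.31 (SD, n = 3) log2 units. The difference was -0.65 ± 0.22 (SE) and was below 0 in all 3 pairs of equal number, at -0.28, -1.26 and -0.43. It did not pass after adjustment over all genes (limma adjusted p = 0.773). This direction goes against the labels, so each direction given here rests on the labels alone. Whether the probes of this row lie in sequence that the reporter allele keeps is not known here. Ptprc, which encodes the leukocyte marker CD45, differed by 0.15 ± 0.22 (SE), and Cd4 by 0.14 ± 0.27 (SE). Foxp3 was not analysed here.

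The 12 genes with the smallest p in each direction are given as values that did not pass (limma adjusted p from 0.540 to 0.773). For all 24 the 3 arrays of each fraction did not overlap, which the choice by smallest p favours. Of all genes tested, 2591 did not overlap, or 13.3% against 10% expected by chance. The largest differences were those of Phf11c, at 1.73 ± 0.23 (SE) or 3.33-fold higher, and Ndrg3, at 1.71 ± 0.23 (SE) or 3.28-fold higher. Ndrg3 differed by 1.70, 1.72 and 1.73 in the 3 pairs. The chromatin remodeller Atrx differed by 1.21, the transcriptional repressor Spen by 1.18, the cohesin subunit Stag1 by 0.94 and the inner nuclear membrane protein Tor1aip1 by 0.93. The kinase Stk38l was 2.30-fold higher, and the ring finger gene Rnf24 was higher by 1.33, the fatty acid elongase Elovl6 by 1.04 and the ganglioside sialyltransferase St8sia1 by 0.87. The interleukin-1 receptor Il1r1 differed by 1.22 ± 0.19 (SE) and the TNF receptor Tnfrsf1a by 1.08 ± 0.21 (SE). Among the lower genes, Pxdc1 differed by -1.68 ± 0.38 (SE) and Il17rb, a subunit of the receptor for interleukin-25, by -1.37 ± 0.26 (SE). The kinase Prkd3 differed by -0.98, and the triglyceride synthesis enzyme Dgat2 by -0.81. Orm1 and Orm3, closely related acute-phase genes that an array may not tell apart, differed by -1.06 and -0.82. The calcium-sensing receptor Casr (-0.72), the collagen prolyl hydroxylase P4ha3 (-0.97), the asparagine synthetase Asns (-0.77), the oxygen sensor Egln3 (-0.84), Prdm6 (-0.84) and Cldnd1 (-0.79) completed the group.

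**Figure D1:**
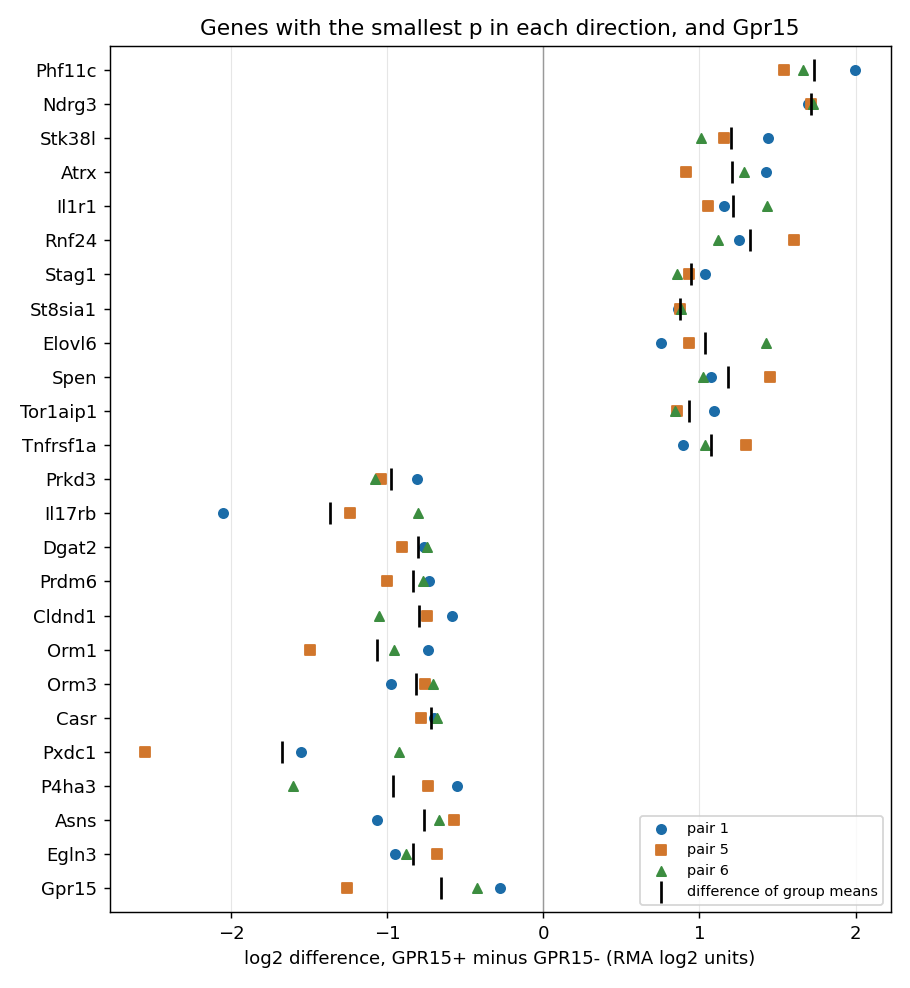
Log2 difference, samples labelled GPR15+ minus GPR15-, of the 12 genes with the smallest p in each direction and of Gpr15, with points for the 3 pairs of equal number and black bars for the difference of group means. Ndrg3 lies near 1.7 in every pair, Phf11c lies above 1.5, and Gpr15 lies below 0 in all 3 pairs.

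The Th17 list was higher in samples labelled GPR15+, with 11 of its 15 measured members above 0 and a median of 0.22 (camera adjusted p = 0.00475). With an estimated correlation the adjusted p from camera was 0.270, and without GPR15+ replicate 5 it was 0.0674. The median was above 0 in each pair, at 0.19, 0.50 and 0.25. No member passed over all genes. Adjusted over the list alone, 5 passed: Tmem176b, a membrane channel protein, at 1.38 ± 0.34 (SE); Il1r1; Ccl20, the ligand of CCR6, at 0.98 ± 0.22 (SE); Il23r at 0.61 ± 0.17 (SE); and Csf2, which encodes GM-CSF, at -0.67 ± 0.18 (SE). With the replicate block 6 passed over the list alone, Tmem176a (0.68) being added. Rora, a nuclear receptor of Th17 cells, lay below 0 at -0.43, and Il23r, Rora and Tmem176a were chosen after their values were seen. Fry gave this list an adjusted p of 0.217 for a shift in 1 direction and of 1.5e-05 for movement in either direction. Il17a, the cytokine that gives Th17 cells their name, differed by 0.07.

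The Th2 list lay in the other direction, with 8 of 10 members below 0 and a median of -0.29, and was not called (camera adjusted p = 0.0825; adjusted p = 0.416 with an estimated correlation). Il17rb passed adjusted over the list alone (limma adjusted p = 0.00761). The Th2 cytokines Il4 (-0.62) and Il5 (-0.47) did not pass, nor did the chemokine receptor Ccr4, which lay above 0 at 0.73. Fry gave an adjusted p of 0.217 for a shift in 1 direction and of 2.49e-06 for either direction. The Th1 list was not called (camera adjusted p = 0.626), and its median was -0.07, which turned sign when arrays were centred on their medians or the intensity trend was removed, and was 0.05 without GPR15- replicate 1. Of its members, Tnf differed by 0.68 and passed over the list alone with the replicate block, and Il18rap, a subunit of the interleukin-18 receptor, differed by -0.65.

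**Figure D2:**
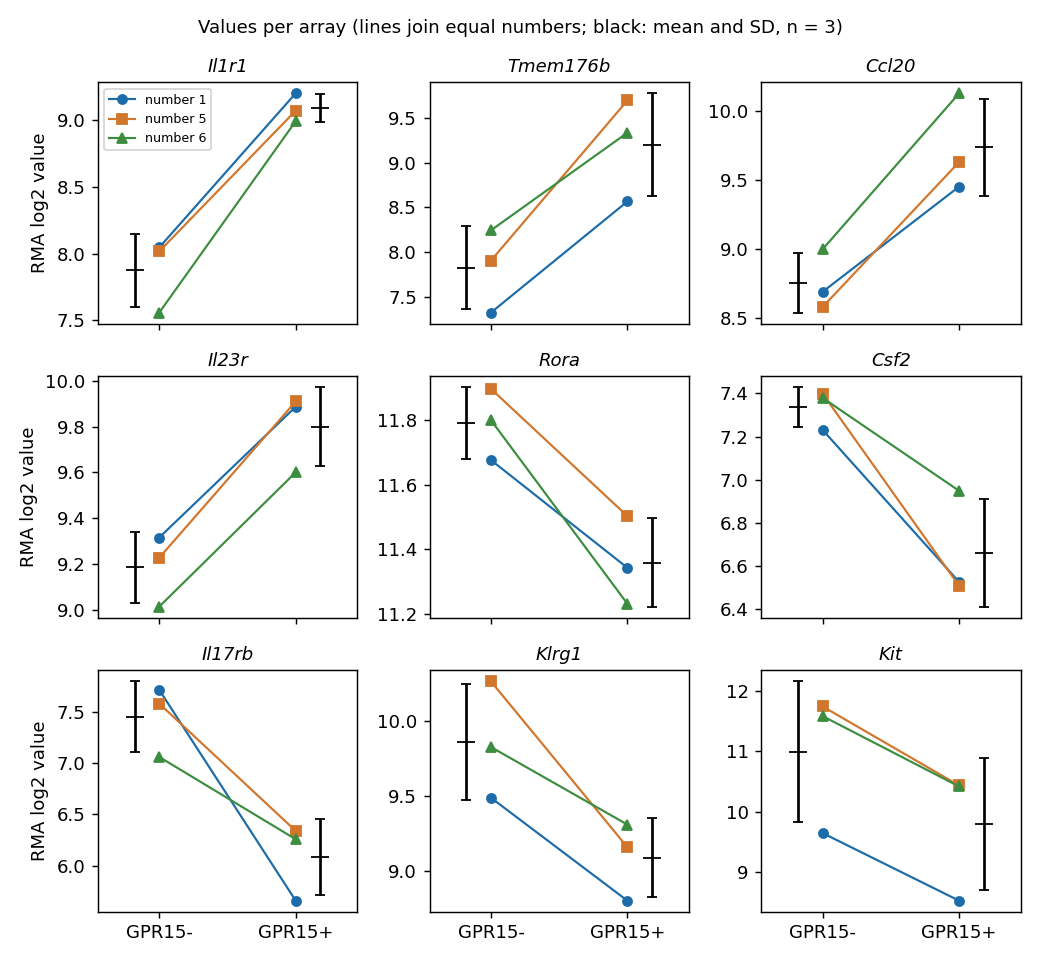
RMA log2 values of 9 genes on each array, with lines joining samples of equal number and black bars for the mean and SD of each fraction (n = 3). Il1r1, Tmem176b, Ccl20 and Il23r lie higher in all 3 samples labelled GPR15+, and Rora, Csf2, Il17rb and Klrg1 lie lower; Kit lies lower within each pair while its level differs between the pairs.

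The naive and central memory list was higher in samples labelled GPR15+, with 11 of 14 members above 0 (camera adjusted p = 1.29e-04; adjusted p = 0.270 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The members with the largest differences were the surface glycoprotein Ly6c1 at 1.15 ± 0.52 (SE), the actin crosslinker Actn1 at 0.92 ± 0.33 (SE), Bach2, a repressor of effector genes, at 0.87 ± 0.37 (SE), and the chromatin organiser Satb1 at 0.74 ± 0.27 (SE). With the replicate block 3 members passed over the list alone, Satb1, Actn1 and Foxp1 (0.68), the last named after its value was seen. The arrays numbered 1, which stood apart in their spread, differed less in this list: the median was 0.13 in pair 1 against 0.51 and 0.50 in pairs 5 and 6. Ly6c1 and Bach2 lay below 0 in pair 1, at -0.23 and -0.23.

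The type I interferon list was higher (median 0.12; 16 of 20 members above 0; camera adjusted p = 0.0318; adjusted p = 0.416 with an estimated correlation). Zbp1, a sensor of nucleic acids, differed by 0.60 and Irf7, a transcription factor of the response, by 0.62, while the interferon-induced Ifit3 differed by -0.56. None passed adjusted over the list alone. The adjusted p from camera was 0.118 without GPR15- replicate 1, 0.0536 without GPR15- replicate 5, 0.117 without GPR15+ replicate 5 and 0.348 without GPR15+ replicate 6, and the median was 0.18 without GPR15- replicate 6, 0.28 without GPR15+ replicate 1 and 0.06 without GPR15+ replicate 6.

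Brighter genes tended to lie higher in samples labelled GPR15+. Across genes, which are not independent replicates, the Spearman correlation of the difference with the mean level was 0.235. In pairs 5 and 6 the median difference went from -0.20 and -0.16 for genes at 5 to 6 log2 units to 0.20 and 0.16 at 9 to 10, and in pair 1 the same bins lay at -0.04 and -0.05. The rise did not go on among the brightest genes, at 10 or more, which lay at 0.13 and 0.10 in pairs 5 and 6 and at -0.10 in pair 1. With this trend removed, the homing, glycolysis and ribosomal lists were no longer called (camera adjusted p = 0.213, 0.230 and 0.598). Their medians less the median of all genes went from 0.17 to 0.03, from 0.26 to 0.13 and from 0.12 to 0.04. As deposited, the homing receptor list had a median of 0.11 (camera adjusted p = 0.00994; adjusted p = 0.346 with an estimated correlation). Its leading members were chemokine receptors on either side of 0, Ccr1 (0.81), Ccr9 (0.77) and Ccr4 (0.73) above and Ccr8 (-0.70) below. The adjusted p from camera was 0.0811 without GPR15- replicate 1 and 0.0674 without GPR15+ replicate 5, and the median was 0.19 without GPR15- replicate 6 and 0.18 without GPR15+ replicate 5. The glycolysis list had a median of 0.20 (camera adjusted p = 0.0318; adjusted p = 0.346 with an estimated correlation), led by the hexokinase Hk1 at 1.42 ± 0.61 (SE). Its adjusted p from camera was 0.164, 0.0536, 0.0853 and 0.104 without GPR15- replicate 1, GPR15- replicate 5, GPR15+ replicate 1 and GPR15+ replicate 5, and its median was 0.08 without GPR15- replicate 1. The ribosomal protein list had a median of 0.05 over 63 genes (camera adjusted p = 0.0304; adjusted p = 0.737 with an estimated correlation), with Rpl35a at 0.41. Its median was -0.15 in pair 1, and -0.05 without GPR15+ replicate 6 (camera adjusted p = 0.955). It was 0.02 without GPR15- replicate 1 (camera adjusted p = 0.166), 0.02 without GPR15+ replicate 5 (camera adjusted p = 0.262) and 0.23 without GPR15+ replicate 1. Without both arrays numbered 1 the homing and glycolysis lists were not called (camera adjusted p = 0.104 and 0.142), and the ribosomal median was 0.18 (camera adjusted p = 4.3e-06). No member of these 3 lists passed adjusted over the list alone.

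**Figure D3:**
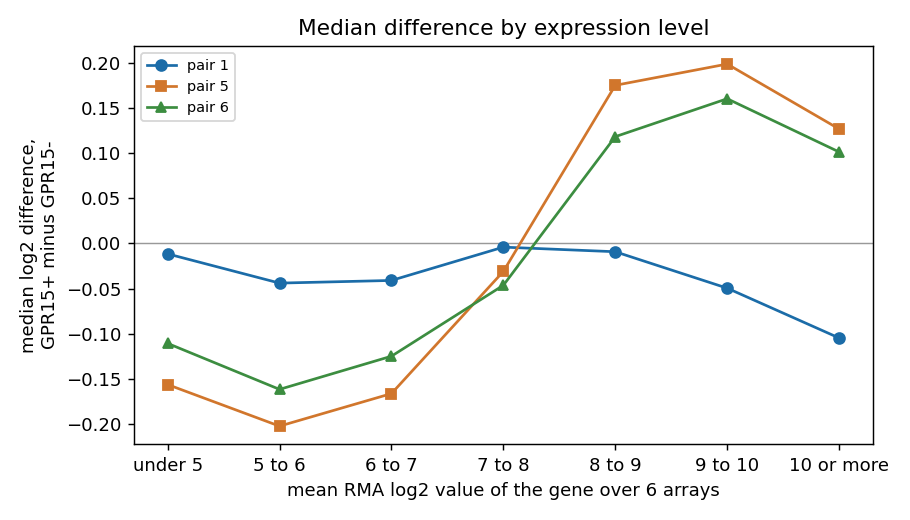
Median log2 difference, samples labelled GPR15+ minus GPR15-, of genes binned by mean RMA log2 value over the 6 arrays, for each pair of equal number. In pairs 5 and 6 genes at 9 to 10 log2 units lie at 0.20 and 0.16, and in pair 1 they lie at -0.05.

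Marker lists of other cell types were tested in the same way. The epithelial list was lower in samples labelled GPR15+, with 15 of 17 members below 0 (camera adjusted p = 0.00994; adjusted p = 0.491 with an estimated correlation), and its median lay below 0 in each pair, at -0.31, -0.33 and -0.29. Its leading members were the microvillus protein Vil1 (-0.59) and the gut epithelial gene Phgr1 (-0.51), and no member passed adjusted over the list alone. Of its 17 members, 6 lay above the median level of all genes. The call was lost without GPR15- replicate 1 (camera adjusted p = 0.0624) and without GPR15+ replicate 5 (camera adjusted p = 0.0674, median -0.12). No other list of these was called. The macrophage list had a median of -0.16 (camera adjusted p = 0.188). It was called without GPR15+ replicate 1 (median -0.42, camera adjusted p = 0.0103), without both arrays numbered 1 (-0.29, 0.0478) and with array weights (-0.28, 0.0145), but not with an estimated correlation (camera adjusted p = 0.737), and its median was -0.10 without GPR15- replicate 1, -0.25 without GPR15- replicate 6 and -0.06 without GPR15+ replicate 6. Its members included Lyz2 at -0.48 and Cybb, a subunit of the phagocyte oxidase, at 1.17. The dendritic cell list had a median of -0.21 (camera adjusted p = 0.282), with H2-Aa at -0.31. The B and plasma cell list had a median of -0.07 (camera adjusted p = 0.452), which turned sign when arrays were centred or the trend removed, with the plasma cell genes Jchain at -1.13 ± 0.55 (SE) and Mzb1 at -0.59. Both were dim, at the 28.9 and 12.1 percentiles of mean level, and Jchain lay at -0.07 in pair 6. Of the 11 members of this list, 1 lay above the median level of all genes. The stromal list had a median of -0.01 (camera adjusted p = 0.937), which turned sign with every rescaling, and Pecam1 lay at 0.45. The list of γδ T and innate lymphoid cell genes had a median of -0.32 over 6 genes (camera adjusted p = 0.188), led by Kit, the receptor for stem cell factor. Kit differed by -1.12, -1.30 and -1.16 in the 3 pairs and passed over the list alone with the replicate block (limma adjusted p = 5.01e-04), not without it. The CD8 T and NK cell list had a median of 0.04 (camera adjusted p = 0.244) over members that lay apart. The granzyme Gzma lay at -1.40 ± 0.37 (SE), and the inhibitory receptor gene Klrc1 and the kinase Txk at 1.07 and 0.76; all 3 passed over the list alone with the block, not without it. The T cell list had a median of 0.14 (camera adjusted p = 0.0819), with Thy1 at 0.46 and the T cell receptor chain Cd247 at 0.32. It was called without GPR15- replicate 6 (camera adjusted p = 0.0197) and without GPR15+ replicate 1 (0.0242, median 0.25), but not with an estimated correlation (camera adjusted p = 0.737), and its median was -0.07 without GPR15- replicate 1 and -0.01 without GPR15+ replicate 5. With 1 array left out, the median of the B and plasma cell list went from -0.15 (without GPR15+ replicate 1) to -0.02 (without GPR15+ replicate 6) and that of the dendritic cell list from -0.31 (without GPR15+ replicate 1) to -0.13 (without GPR15- replicate 6). The stromal list went from -0.11 (without GPR15+ replicate 1) to 0.07 (without GPR15- replicate 1) and the CD8 T and NK cell list from -0.04 (without GPR15- replicate 5) to 0.11 (without GPR15+ replicate 1).

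**Figure D4:**
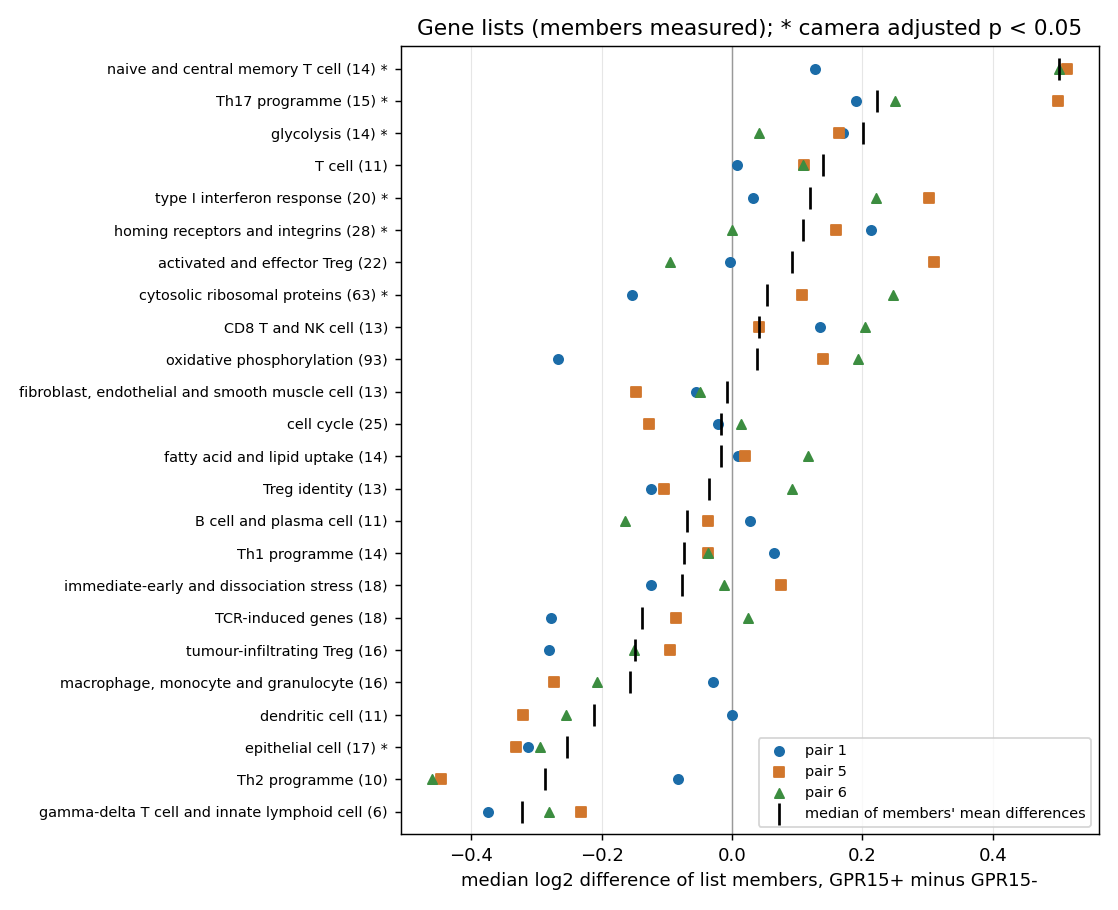
Median log2 difference of the members of each of 24 gene lists, samples labelled GPR15+ minus GPR15-, with points for the 3 pairs of equal number, black bars for the median of the members' mean differences and asterisks for lists called by camera. The naive and central memory list lies highest at 0.50, and the epithelial list lies near -0.3 in every pair.

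Lists of the Treg programme were not called. The Treg identity list had a median of -0.04 (camera adjusted p = 0.471), which turned sign when arrays were centred and went from -0.26 without GPR15+ replicate 6 to 0.36 without GPR15+ replicate 1, with the Treg transcription factor Ikzf2 at -0.52, the cytokine signalling inhibitor Socs2 at 0.56 and Gpr83 at 0.46. The activated and effector list had a median of 0.09 (camera adjusted p = 0.188), which turned sign with quantile normalization. It was called without GPR15+ replicate 1 (camera adjusted p = 0.0273; adjusted p = 0.737 with an estimated correlation over all arrays), and its median was -0.15 without GPR15+ replicate 5 and -0.03 without GPR15- replicate 1. Its member Lag3, an inhibitory receptor that binds MHC class II, was higher at 1.07 ± 0.21 (SE) and passed adjusted over the list alone (limma adjusted p = 0.0204). The suppressive cytokine Il10 (0.79) and the inhibitory receptor Klrg1 (-0.77) passed over the list alone with the replicate block, and the costimulatory receptor Tnfrsf9 (-0.49) did not. Across the 24 lists 7 members passed adjusted over the list alone, and 19 with the replicate block. Without GPR15- replicate 5 that count was 2, without GPR15+ replicate 5 it was 4, and without GPR15+ replicate 1 it was 36. The list of tumour-infiltrating Treg genes had a median of -0.15 (camera adjusted p = 0.238), with the chemokine receptor Ccr8 at -0.70 and Layn at -0.54, and a median of 0.00 without GPR15+ replicate 1. It was called with quantile normalization (camera adjusted p = 0.0399) and once the intensity trend was removed (0.0318), as was the list of γδ T and innate lymphoid cell genes (0.0421 and 0.0358). With an estimated correlation the adjusted p from camera was 0.491 for both.

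The other lists of activation and metabolism were not called as deposited. Genes induced by the T cell receptor had a median of -0.14 (camera adjusted p = 0.626), with Egr2 at 0.62, Myc at -0.55 and Irf4 at 0.45. Immediate-early and dissociation stress genes had a median of -0.08 (camera adjusted p = 0.471), with Btg2 at 0.72 and Ier3 at -0.42. Cell cycle genes had a median of -0.02 (camera adjusted p = 0.937), which turned sign with every rescaling, and the cyclin Ccnb2 lay 2.31-fold lower and Birc5 at -0.54. Ccnb2 passed over the list alone with the replicate block. Oxidative phosphorylation genes had a median of 0.04 over 93 genes (camera adjusted p = 0.0537), at -0.27 in pair 1 against 0.14 and 0.19 in pairs 5 and 6, and below 0 with quantile normalization. This list was called without GPR15+ replicate 1 (median 0.31, camera adjusted p = 1.79e-08), without GPR15- replicate 6 (0.12, 0.00325), without both arrays numbered 1 (0.18, 4.01e-06), with array weights (0.24, 7.53e-08) and with every row as its own feature (0.04, 0.0448). With an estimated correlation, which was 0.383 for this list, it was not called (camera adjusted p = 0.737). Its median was -0.12 without GPR15+ replicate 6, and -0.08 without GPR15- replicate 1 or GPR15+ replicate 5. Genes of fatty acid and lipid uptake had a median of -0.02 (camera adjusted p = 0.449), above 0 when arrays were centred, with the acyl-CoA synthetase Acsl5 at 0.59. For the Treg identity, Th1, immediate-early and fatty acid lists the means (0.03, 0.03, 0.00 and 0.02) lay above 0 while the medians lay below it. Camera's direction was up for these lists and for the cell cycle list (mean -0.04). Camera compares a list with all other genes and not with 0, and the median difference of all genes was -0.06. With 1 array left out, the median of the T cell receptor-induced list went from -0.21 (without GPR15+ replicate 5) to -0.02 (without GPR15+ replicate 1), and that of the immediate-early list reached 0.06 (without GPR15+ replicate 1). The cell cycle median went from -0.05 (without GPR15- replicate 6) to 0.09 (without GPR15+ replicate 5), and the fatty acid median from -0.07 (without GPR15- replicate 1) to 0.07 (without GPR15+ replicate 5). The mitochondrially encoded list had 0 measured genes and was not tested.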

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

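Leaving out both arrays numbered 1, removing the intensity trend and joining the replicate block to other settings were chosen after seeing the data, and the other alternatives were fixed before the data were examined.

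The gene counts stayed at 0 higher and 0 lower in all but 2 alternatives. Array weights gave 979 higher and 1195 lower, but their estimation stopped before it converged, with weights from 0.19 for GPR15+ replicate 1 to 6.56 for GPR15+ replicate 6. An unadjusted p under 0.05 with at least 2-fold difference gave 73 and 11, as this rule does not correct for the number of genes. With array weights Gpr15 was called at -0.59 (limma adjusted p = 0.0461), and the cause was not tested.

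The 7 list calls were made by camera at the preset correlation. With the correlation estimated 0 lists were called, and 0 with the block added. For the Th17 and glycolysis lists the estimates, 0.00106 and 0.00822, lay below the preset 0.01. A larger correlation between members therefore does not account for the loss of these calls. Camera also reads its statistic at fewer degrees of freedom under this setting. For the Th17 list its unadjusted p rose from 3.96e-04 to 0.0198 although the correlation was lower. The other called lists had estimates above the preset, from 0.0220 (homing) to 0.479 (ribosomal), so both changes acted on them. Without the 40% dimmest genes camera called 3, and 3 with the block added. Fry called 0 by direction and 2 in either direction. Leaving out 1 array moved the count from 1 (without GPR15+ replicate 5) to 10 (without GPR15+ replicate 1). The cause was not tested. Over 17 alternatives at the preset correlation, those of eBayes left out because camera does not use them, the naive list was called in 17 (camera adjusted p from 6.71e-05 to 0.00583), Th17 in 16, epithelial in 15, interferon in 11, ribosomal in 9, homing in 8 and glycolysis in 6.

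The count of 7 members past the threshold adjusted over the list alone became 19 with the replicate block, 21 with the block and the trend removed, 26 with the block and eBayes with trend and robust settings, and 22 with the block and the dim filter. It became 100 with array weights, 40 without both arrays numbered 1, and 2 (without GPR15- replicate 5) to 36 (without GPR15+ replicate 1) with 1 array left out. The cause was not tested. The block changed no other call.

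Values near 0 turned sign, and are given here to 3 digits. Cd4 lay at -0.127 with array weights, at -0.0678 without both arrays numbered 1, and from -0.143 (without GPR15- replicate 1) to 0.297 with 1 array left out. Il7r lay at -0.0332 with quantile normalization, -0.145 with array weights, -0.0124 without both arrays numbered 1, -0.00670 with the trend removed (-0.00670 with the block as well), and from -0.0603 (without GPR15+ replicate 5) to 0.150 with 1 array left out. Lgals4 lay at -0.197 with array weights, -0.137 without both arrays numbered 1, and from -0.0915 (without GPR15+ replicate 1) to 0.220 with 1 array left out. Il17a lay at -0.0871 with array weights, -0.155 without both arrays numbered 1, and from -0.103 (without GPR15+ replicate 1) to 0.179 with 1 array left out. Cdh1 lay at 0.0513 with array weights, and from -0.202 to 0.136 (without GPR15+ replicate 5) with 1 array left out. Leaving out 1 array moved Ptprc from -0.0492 (without GPR15+ replicate 1) to 0.284, Ccr7 from -0.348 to 0.0454 (without GPR15+ replicate 5), and the ribosomal median from -0.0512 (without GPR15+ replicate 6) to 0.231. The cause was not tested.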

Other observations

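All tests in this part were chosen after the result was seen, except the counts of splits for genes and for lists and the lists without both arrays numbered 1. That omission was chosen once the spread of those arrays was known, but before its own result was.

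Kit, Egr2 and St8sia1 differed by nearly the same amount in each pair. Kit lay at 9.65, 11.7 and 11.6 log2 units in the samples labelled GPR15- and numbered 1, 5 and 6, and at 8.53, 10.4 and 10.4 in those labelled GPR15+. Egr2, a transcription factor induced by the T cell receptor, differed by 0.64, 0.62 and 0.59, and St8sia1 by 0.87, 0.87 and 0.88. None of these passed over all genes.

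Removing the intensity trend left the naive, Th17, interferon and epithelial lists called at the preset correlation (highest adjusted p from camera 0.0318). The naive and Th17 medians less that of all genes went from 0.56 ± 0.11 to 0.42 ± 0.12 and from 0.29 ± 0.15 to 0.24 ± 0.14 (SE over members). The interferon and epithelial ones went from 0.18 ± 0.07 to 0.22 ± 0.07 and from -0.19 ± 0.04 to -0.16 ± 0.04. Here and below, the SE over members is that of their mean and takes members as independent. It does not measure the spread between arrays. As deposited, none of the 4 was called with an estimated correlation (camera adjusted p = 0.270, 0.270, 0.416 and 0.491). These 4 lists were grouped because their calls stayed after the removal, so their adjusted p decides nothing about the trend as their source. The same step ended the calls of the homing, glycolysis and ribosomal lists (lowest adjusted p from camera 0.213), and the same measure went from 0.17 ± 0.07 to 0.03 ± 0.07, from 0.26 ± 0.11 to 0.13 ± 0.13 and from 0.12 ± 0.02 to 0.04 ± 0.02 (SE over members). These 3 lists were grouped because their calls ended, so the trend as their source stays open. Without both arrays numbered 1, whose values are compressed, the highest adjusted p from camera of the 4 lists was 0.0115. At the preset correlation this argues against those 2 arrays as the source of the 4 calls. The homing and glycolysis lists were then not called (0.104 and 0.142). Without GPR15- replicate 1 alone the interferon and epithelial lists were not called (camera adjusted p = 0.118 and 0.0624), while the naive and Th17 lists were.

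Other splits of the 6 arrays into 3 and 3 were counted for comparison, and 10 splits are too few for a share under 0.05. The real split called 7 lists and 0 genes; 4 of the 10, itself included, called as many lists (highest other 9), and 10 called as many genes (highest other 0). With array weights 2 of the 10 called as many genes (2174, highest other 3201). The 4 splits that kept the arrays numbered 1 together called 9, 8, 7 and 4 lists, with 3770, 3479, 483 and 1025 genes at an unadjusted p under 0.05 against the real 1214. The other 3 splits that part all pairs, as the real one does, called 0, 3 and 4 lists.

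A larger share of naive T cells in the samples labelled GPR15+ would raise the abundant members together, but of the 3 most abundant, Satb1 lay at 0.74, Il7r at 0.06 and Ccr7 at -0.16, which is -0.68 of its standard error and decides nothing. The naive list shares 3 of its 14 genes with other lists, and the gate on the Foxp3 reporter would remove naive T cells other than Tregs. No biological explanation was tested. For the epithelial list, RNA of epithelial cells in the samples labelled GPR15- may account for a lower level: the 5 most abundant markers had a median of -0.25, with Vil1 at -0.59, Phgr1 at -0.51, Muc2 at -0.25, Cdh1 at -0.09 and Lgals4 at 0.08. They did not move alike, so this source stays open, although the gates on CD4 and the Foxp3 reporter would remove epithelial cells.

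Gpr15 lay lower in the samples labelled GPR15+ in 3 of 3 pairs, so labels exchanged within 1 pair alone cannot account for it. An exchange of the groups in all pairs cannot be told apart from the other explanations, since 0 rows were named for the green reporter. Where a reporter replaces part of Gpr15, the row need not follow the gate. Both fractions came from mice with the reporter, so this alone would not predict a lower level in samples labelled GPR15+. Whether it plays a part stays open, because the probe positions and the map of the allele were not used here. The level of the row, at the 85.1 percentile of all genes, does not decide it. No biological explanation was tested.

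The mean difference of the Th17 list less that of the Th2 list was 0.58, and 0.41, 0.69 and 0.65 in the pairs numbered 1, 5 and 6. Members of both lists went against their list, Csf2 (-0.67) and Rora (-0.43) in the first and Ccr4 (0.73) in the second. Neither list was called with an estimated correlation (camera adjusted p = 0.270 and 0.416). These 2 lists were picked from 24 after their results were seen, so the place of their difference at the 100th percentile of 10000 pairs of random lists matched on mean level decides nothing.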
